A study of Rattus norvegicus with 3 samples.

How the data were processed

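The deposited values were log2 RMA expression levels (robust multi-array average, which corrects background, quantile-normalizes the arrays and summarises the probes of a set by median polish). RMA is named in the submitters' processing notes without a version. The log base is not stated in the table, and log2 was taken because RMA returns log2 values and the deposited range fits it. The chip description, annotation and genome build used by the authors are not given in the sources used here, and no coordinates were printed for that reason. Per the labels' protocols, RNA was pooled from 6 rats per group, only RNA with an integrity number above 8 was used, and 100 ng went into each labelling. The contralateral leg was a sham control per the labels; it was not analysed here. Whether rats in the 3 pools were kept and processed together is not given.

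Values were used as deposited. Of 29214 probe sets, 15310 had a single gene symbol in the platform annotation, 323 had several and 13581 were not listed; the last 2 kinds were left out. Of the single-gene probe sets, 15279 had an Entrez gene number in the RefSeq gene table (assembly GRCr8, used for names only), and 0 symbols needed an update. Of the gene list symbols, 5 were updated through a synonym. For each of 14506 genes the probe set with the highest mean over the 3 arrays was kept; 527 genes had more than 1. Genes whose mean was under the 25th percentile of all genes (5.34) were left out as dim, which left 10879.

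With 1 array per group there was no significance test, no p-value and no standard deviation between arrays of a group. Each of 3 comparisons was the difference of log2 values between a pair of arrays. Genes were counted when they differed by at least 1.5-fold. For gene lists, the median difference over members, its 95% order-statistic interval over those members, and its percentile among 10000 random lists matched on size and mean level (20 level bins) were computed. A list stood apart below percentile 2.5 or above 97.5. Lists needed at least 5 measured genes; of 47 fixed lists, the neutrophil list had only 2 and was left out. Lists, thresholds, the naming rule and most alternatives were chosen before the data were examined. Lists share members: 12 of the 18 PPAR targets are in another list, and the PPAR target and lipid droplet lists contain Plin2 and Plin5.

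Named genes were the perilipins, the 10 genes with the largest difference each way past the dim filter and 1.5-fold, up to 4 leading members of each list that stood apart with the largest member against it, and up to 5 genes each way that passed 1.5-fold on both arrays against the empty vector. For lists on oxidative metabolism, lipid droplets and insulin signalling that did not stand apart, up to 3 extreme members were named. Symbols beginning with LOC, RGD, Olr, Vom, Mir, Snor or ENSR were counted but not named. The Plin5 and Plin2 differences share the empty vector array. Their correlation was therefore set beside 100 simulated sets of unchanged arrays, with noise drawn from the Plin5 minus empty vector differences of genes of similar level.

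The RMA summary affects small differences. Of all probe sets, 11311 (38.7%) had exactly equal values on all 3 arrays, from 61.4% among the dimmest 10% to 6.33% among the brightest, and 40.8% of the equal ones lay in the dimmest 25%. Of genes past the dim filter, 2673 were equal on all 3 arrays, and 4368 were equal between Plin5 and empty vector. List medians of 0.00 can be set by such genes. In simulated unchanged probe sets summarised by median polish over 3 arrays, 16.3%, 16.5% and 79.4% of sets with 5, 10 and 25 probes were equal; the number of probes per set is not in the table, and these probe numbers were chosen after the equal values were seen. Normalization that forces arrays to a common distribution also hides any change in total RNA, and bright genes can be compressed on arrays.

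List statistics were tested on simulated data with the differences of each comparison, shuffled among genes of similar level. Members of a simulated list therefore varied independently, which those of a real list do not. Shifts were added to genes of equal value too, so recovery on real arrays may be lower. Among 46 lists with no shift, 1, 4 and 0 stood apart for Plin5 against empty vector, Plin2 against empty vector and Plin5 against Plin2. Of 24 lists shifted by 0.20 log2 units, 24, 15 and 8 were called higher over 10879 genes, so small shifts are easily missed in the comparisons with the Plin2 array. Alternatives covered the fold threshold, the dim filter, centring, quantile normalization, a loess correction for level, averaging of probe sets, and the mean in place of the median of a list. After seeing the data, 3 more were added: the dim filter from only the compared arrays, lists without genes of equal value, and lists without the introduced genes. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.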

Results

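RNA from rat tibialis anterior muscle was measured on whole-transcript gene arrays 8 days after plasmid DNA had been electroporated into the muscle. The animals were male Wistar rats, 11 weeks old, kept for 3 weeks on a diet with 45% of its energy as fat, and the plasmid (150 µg) was given after 2 weeks of that diet. There were 3 groups with 1 array each. The plasmid carried Plin2 (adipose differentiation-related protein, ADRP), Plin5 (OXPAT) or no insert (empty vector). Perilipins are proteins that coat lipid droplets. Each array held RNA pooled from 6 rats, so there were no replicates and no spread between animals could be measured. None of the differences below was tested against such a spread. The number of arrays limits the precision of every value. The table held 29214 probe sets per array on the log2 scale, with array medians of 6.38 (empty vector), 6.40 (Plin2) and 6.37 (Plin5). After 1 probe set per gene was kept and dim genes were removed, 10879 genes were compared.

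Each introduced gene had its highest level on its own array. The Plin5 probe set (10931038) stood at 7.52 on the empty vector array and 8.30 on the Plin5 array, a log2 difference of 0.78 (1.72-fold). On the Plin2 array it stood at 6.79, which was −0.73 against the empty vector. The Plin2 probe set (10877907) stood at 9.99 on the empty vector array and 10.71 on the Plin2 array, a difference of 0.71 (1.64-fold), and at 10.08 on the Plin5 array, a difference of 0.09. Plin1 (5.94) and Plin3 (7.10) had exactly equal values on all 3 arrays, and Plin4 was not analysed here. The labels do not give the species of the introduced cDNAs, so how much plasmid transcript the rat probes detected is unknown.

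**Figure D1:**
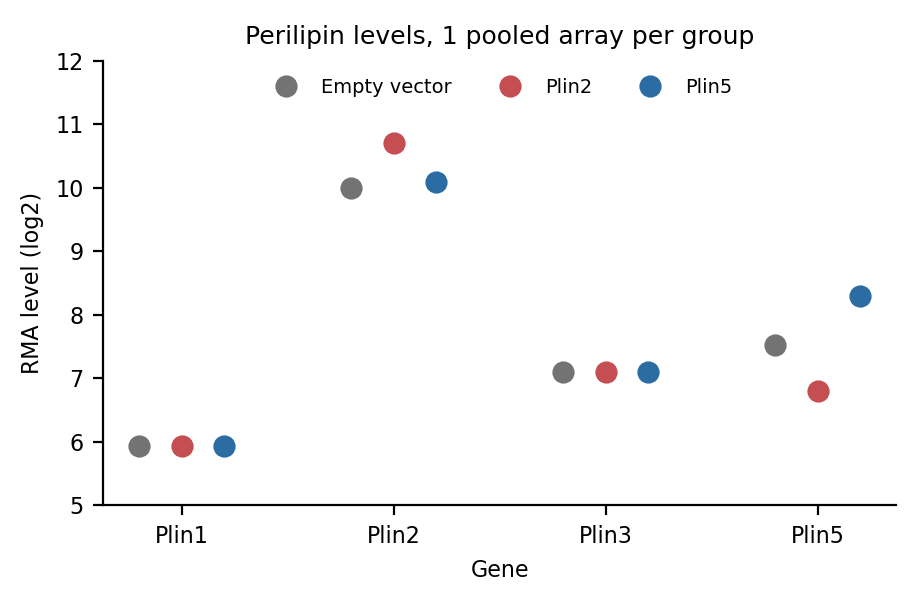
Levels (log2) of 4 perilipin genes on the empty vector, Plin2 and Plin5 arrays; each point is 1 array of RNA pooled from 6 rats and there are no error bars. Plin2 was highest on the Plin2 array (10.71) and Plin5 on the Plin5 array (8.30), while Plin5 was lowest on the Plin2 array (6.79).

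The comparison of Plin5 with the empty vector addressed whether Plin5 alters oxidative gene expression in muscle. Genes of mitochondrial energy metabolism were slightly and broadly higher on the Plin5 array: 63 of 72 measured subunits of the respiratory chain and ATP synthase were above the empty vector, by a median of 0.10 log2 units. All 21 measured genes of mitochondrial fatty acid oxidation were higher, with a median of 0.18 (1.14-fold). Slow fibre genes were also higher (median 0.22). Macrophage markers (−0.47) and tendon markers (−0.49) were lower on the same array, by larger amounts. Of 10879 genes, 24 were higher and 154 lower by at least 1.5-fold.

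Of the respiratory chain lists, complex I subunits had a median difference of 0.10 (31 of 32 genes above 0), complex II and III subunits 0.11 (11 of 12), complex IV subunits 0.08 (9 of 13) and ATP synthase subunits 0.07 (12 of 15). Each of these medians stood apart from 10000 random lists of the same size and level, at percentiles from 99.6 to 100. The differences of single subunits were small. The highest were Cox7b (0.29), Ndufa5 (0.28), Sdhb (0.27), Ndufb4 (0.25) and Atp5pf (0.24), and the lowest was Atp5if1 (−0.12), the inhibitor of ATP synthase. No subunit of these 4 lists reached 1.5-fold. In the tricarboxylic acid cycle list, which includes pyruvate dehydrogenase, 15 of 16 genes were above 0 (median 0.12), among them Pdhb (0.26) and Dld (0.23). Mitochondrial ribosomal proteins had a median of 0.05, with 18 of 29 genes above 0. Macrophage and tendon markers were lower on this array, as given above.

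Fatty acid oxidation genes were led by Decr1 (0.28), Hadh (0.27), Acsl1 (0.25) and Echs1 (0.25), all enzymes that activate or break down fatty acids. PPAR target genes of muscle had a median of 0.18, with 16 of 18 above 0. Plin5 itself is in that list; the next highest were Angptl4 (0.58), an inhibitor of lipoprotein lipase, the fatty acid transporter Cd36 (0.28) and the fatty acid binding protein Fabp3 (0.26), while the uncoupling protein Ucp2 was lower (−0.28). Regulators of the PPAR and PGC-1 families had a median of 0.05, with Perm1 at 0.41, Ppargc1a at 0.27 and Ppara at 0.24, against −0.49 for Pparg. Peroxisomal fatty acid oxidation stood at 0.06 (0.10 after median-centring), with Ehhadh at 0.21. Fatty acid uptake and handling stood at 0.05, a list that no longer stood apart when dim genes were kept (0.01, percentile 96.5) and stood at 0.08 after median-centring. These groups too were measured beside the lower macrophage (−0.47) and tendon (−0.49) markers.

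The lipid droplet list (median 0.00, percentile 53.8) and the insulin signalling list (0.00, percentile 56.3) did not stand apart from random lists. In the droplet list, 5 of 15 genes had exactly equal values on both arrays, Plin5 was at 0.78, and G0s2, an inhibitor of adipose triglyceride lipase, was at −0.28. In the insulin signalling list, the lowest genes were Pik3cb (−0.63) and Trib3 (−0.38), and Grb14, an adaptor of the insulin receptor, was at 0.27. Glycolysis and glycogen genes (0.01, percentile 89.9) and fast fibre genes (0.01, percentile 79.1) did not stand apart either; 10 of the 23 glycolysis and 13 of the 15 fast fibre genes were brighter than any fatty acid oxidation gene. Of 14 slow fibre genes, 12 were above 0, with Ankrd2 at 0.54, the slow myosin heavy chain Myh7 at 0.44, Myl2 at 0.38 and Tnnt1 at 0.38.

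Macrophage markers were lower by at least 1.2-fold for 16 of 23 genes, led by Trem2 (−1.33), Clec4a1 (−0.77), Adgre1 (−0.69) and C1qc (−0.66), while the Fc receptor Fcgr2b was higher (0.48). All 9 tendon markers were lower, including the matrix proteins Chad (−1.94), Fmod (−1.17) and Kera (−1.03) and the membrane protein Tnmd (−1.39). Genes of muscle injury and regeneration were lower (median −0.23; 18 of 19 below 0), with the fusion factor Mymk at −1.24 and the fetal acetylcholine receptor subunit Chrng at −0.55. Extracellular matrix genes had a median of −0.14 (18 of 22 below 0), including Col12a1 (−0.44). Cytosolic ribosomal proteins had a median of −0.08 (33 of 38 below 0). Markers of T, natural killer and B cells had a median of −0.23, with Gzmk at −0.76 and the granzyme Gzma at 1.25, and that list no longer stood apart by its mean (−0.12, percentile 3.68).

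Interferon response genes went both ways on the Plin5 array. The list stood apart downward (median −0.26), with 14 of 28 genes lower and 9 higher by at least 1.2-fold. The antiviral genes Mx2 (−1.76), Oasl (−1.17), Irf7 (−1.14) and Oas1a (−0.75) were lower, and the chemokine Cxcl9 (0.84) was higher. Inflammatory mediators stood apart upward (median 0.04), with 8 of 21 genes higher and 3 lower by at least 1.2-fold: Spp1 (1.02), the monocyte chemokine Ccl2 (0.88), Cxcl9 and Nos2 (0.72) were higher and Cxcl16 (−0.67) was lower. The genes with the largest differences upward were Gzma (1.25), Ccl12 (1.09), Spp1 (1.02), Acod1 (0.97), Cxcl11 (0.95), Fcnb (0.91), Ifng (0.91) and Ass1 (0.91). Those with the largest differences downward were the embryonic globin Hbe1 (−3.05), Cd5l (−2.52), Klra5 (−2.10), Ly49i7 (−1.94), Chad, Jchain (−1.85), Mx2, Ly49si1 (−1.71), Il7r (−1.56) and Defb52 (−1.53). On the Plin5 array Hbe1 (4.68), Cd5l (4.48), Klra5 (4.74) and Ly49si1 (4.52) lay under the dim level of 5.34. Ifng (5.24) lay under it on the empty vector array. The size and rank of these differences are therefore uncertain. Klra5, Ly49i7 and Ly49si1 belong to a family of near-identical receptors, so their values are uncertain.

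Altogether 16 of 46 gene lists stood apart upward and 11 downward in this comparison, past the percentile limits set among random lists, where 2.3 would do so by chance if the genes of a list varied independently. Genes of a list do vary together, so the percentile describes these arrays and is not a p-value. Small medians depended on the setting: median-centring gave −0.038 for cytosolic ribosomal proteins, 0.11 for ATP synthase (0.04 after quantile normalization) and 0.09 for mitochondrial ribosomal proteins and for the PPAR and PGC-1 regulators, and means gave 0.19 for inflammatory mediators and −0.76 for tendon markers.

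The comparison of Plin2 with the empty vector set a different droplet protein against the same control. The Plin2 array differed far more from the empty vector than the Plin5 array did, with 962 genes higher and 631 lower by at least 1.5-fold. Immune genes were higher: macrophage markers by a median of 1.06, interferon response genes by 1.13 and markers of T, natural killer and B cells by 0.96. Genes of mitochondrial metabolism were lower, with fatty acid oxidation at −0.72 and complex I at −0.63. Glycolysis and glycogen genes were lower as well (−0.51). The Plin2 plasmid also had a backbone different from that of the other plasmids, so backbone and insert differ together on this array.

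All 32 complex I subunits were lower by at least 1.2-fold, among them Ndufa3 (−0.84), Ndufb4 (−0.83) and Ndufs3 (−0.77). All 12 complex II and III subunits were lower by that amount (median −0.55), with Uqcrq at −1.01 and Sdhb at −0.73. Complex IV subunits had a median of −0.50, with 10 of 13 lower, and Cox8a was higher (0.26). ATP synthase subunits had a median of −0.39, with Atp5mc1 at −0.79. Neither of the last lists stood apart in every setting: complex IV did not by its mean (−0.34, percentile 2.97), and ATP synthase did not after a loess correction for level (−0.34, percentile 2.51). In the tricarboxylic acid cycle list all 16 genes were below 0 (median −0.56), including Mdh1 (−0.81) and Dlat (−0.79). Mitochondrial ribosomal proteins had a median of −0.36.

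All 21 fatty acid oxidation genes were lower by at least 1.2-fold and 18 of them by at least 1.5-fold, including Acadm (−1.07), Hadh (−1.04), the carnitine carrier Slc25a20 (−1.01) and Acadvl (−0.91). PPAR target genes had a median of −0.63, with 13 of 18 lower by at least 1.2-fold, including Fabp3 (−1.14) and Ech1 (−1.03), and 4 higher: Ucp2 (0.83), Angptl4 (0.83), Plin2 itself and Cpt1a (0.57). Of the PPAR and PGC-1 regulators, Perm1 (−1.97), Ppara (−1.50), Esrrg (−1.12) and Rxrg (−0.95) were lower and Pparg (0.55) was higher (median −0.43). Within glycolysis and glycogen metabolism all 23 genes were below 0, with Pfkfb1 at −2.01, the muscle fructose bisphosphatase Fbp2 at −1.73 and the phosphorylase kinase subunit Phkg1 at −1.53. Insulin signalling (−0.08, percentile 16.7) and the lipid droplet list (0.00, percentile 46.8) did not stand apart. Their extreme members were Grb14 (−1.02), the glucose transporter Slc2a4 (−0.95) and Irs1 (−0.74) for insulin signalling, and Fitm2 (−1.30) for the lipid droplet list. Slow fibre genes (−0.26, percentile 4.48) and fast fibre genes (−0.27, percentile 17.9) did not stand apart. All 15 fast fibre genes were nevertheless below 0, 9 of them by at least 1.2-fold. Random lists matched to them on level had a median of −0.14, so bright genes in general were lower on this array. Of the 14 slow fibre genes, 6 were lower by at least 1.5-fold and 5 were above 0. Among the lower ones, Myh7 stood at 9.42 against 11.17 on the empty vector array, and Myl2 at 8.55 against 10.29. Macrophage markers were higher on this array by the 1.06 given above.

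Macrophage markers were higher by at least 1.2-fold for 22 of 23 genes, led by Trem2 (1.96), Gpnmb (1.44), Fcgr1a (1.44) and Mpeg1 (1.42). All 28 interferon response genes were higher by that amount, including Cxcl10 (1.93), Ifit3 (1.72), Oasl (1.66) and Rsad2 (1.65). Of the markers of T, natural killer and B cells, 20 of 21 were higher by at least 1.2-fold. They were led by Gzmb (2.14), Gzma (2.07), Cd8a (1.54) and the perforin gene Prf1 (1.46). Inflammatory mediators had a median of 0.95; Spp1, which encodes osteopontin, was higher by 4.23 (18.8-fold). Antigen presentation genes had a median of 0.67, including Tap1 (1.14) and Ctss (1.07). Mast cell markers were lower (−0.40), with the carboxypeptidase Cpa3 at −1.20. Endothelial markers (0.00, percentile 45.0) and fibroblast markers (0.11, percentile 95.6) did not stand apart.

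Genes of muscle injury and regeneration were higher (median 0.70), including Mymk (1.41), the acetylcholine receptor subunit Chrna1 (1.12) and the myogenic factor Myf5 (1.11), whereas Mstn, which encodes myostatin, was lower (−0.70). Cell cycle genes had a median of 0.54, and all 23 were above 0, with Rrm2 at 0.89 and Top2a at 0.82. Extracellular matrix genes had a median of 0.42, including Timp1 (1.29) and Thbs1 (1.07). The unfolded protein response list stood at 0.39, with Asns at 1.42 and Sdf2l1 at 0.83. The largest differences upward after Spp1 were Tnn (2.86), Defb52 (2.85), Clec2dl1 (2.29), Cxcl11 (2.29), Gzmb, Gzma, Sucnr1 (2.04) and Ccl12 (1.99). Tnn (5.24) and Clec2dl1 (4.87) lay under the dim level of 5.34 on the empty vector array, so the size and rank of their differences are uncertain. The largest downward were Lgi3 (−2.28), Ostn (−2.18), the water channel Aqp4 (−2.04), Pfkfb1, Perm1, Scn4b (−1.82), St8sia5 (−1.81), Lgi2 (−1.81), Mlxipl (−1.77) and the amino acid transporter Slc38a3 (−1.76). In this comparison 13 lists stood apart upward and 16 downward. PPAR targets stood at −0.40 by their mean, and mast cell markers at −0.06 when dim genes were kept. When each array was centred on its median gene, the counts were 775 higher and 819 lower, so the larger side depended on the centring.

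**Figure D2:**
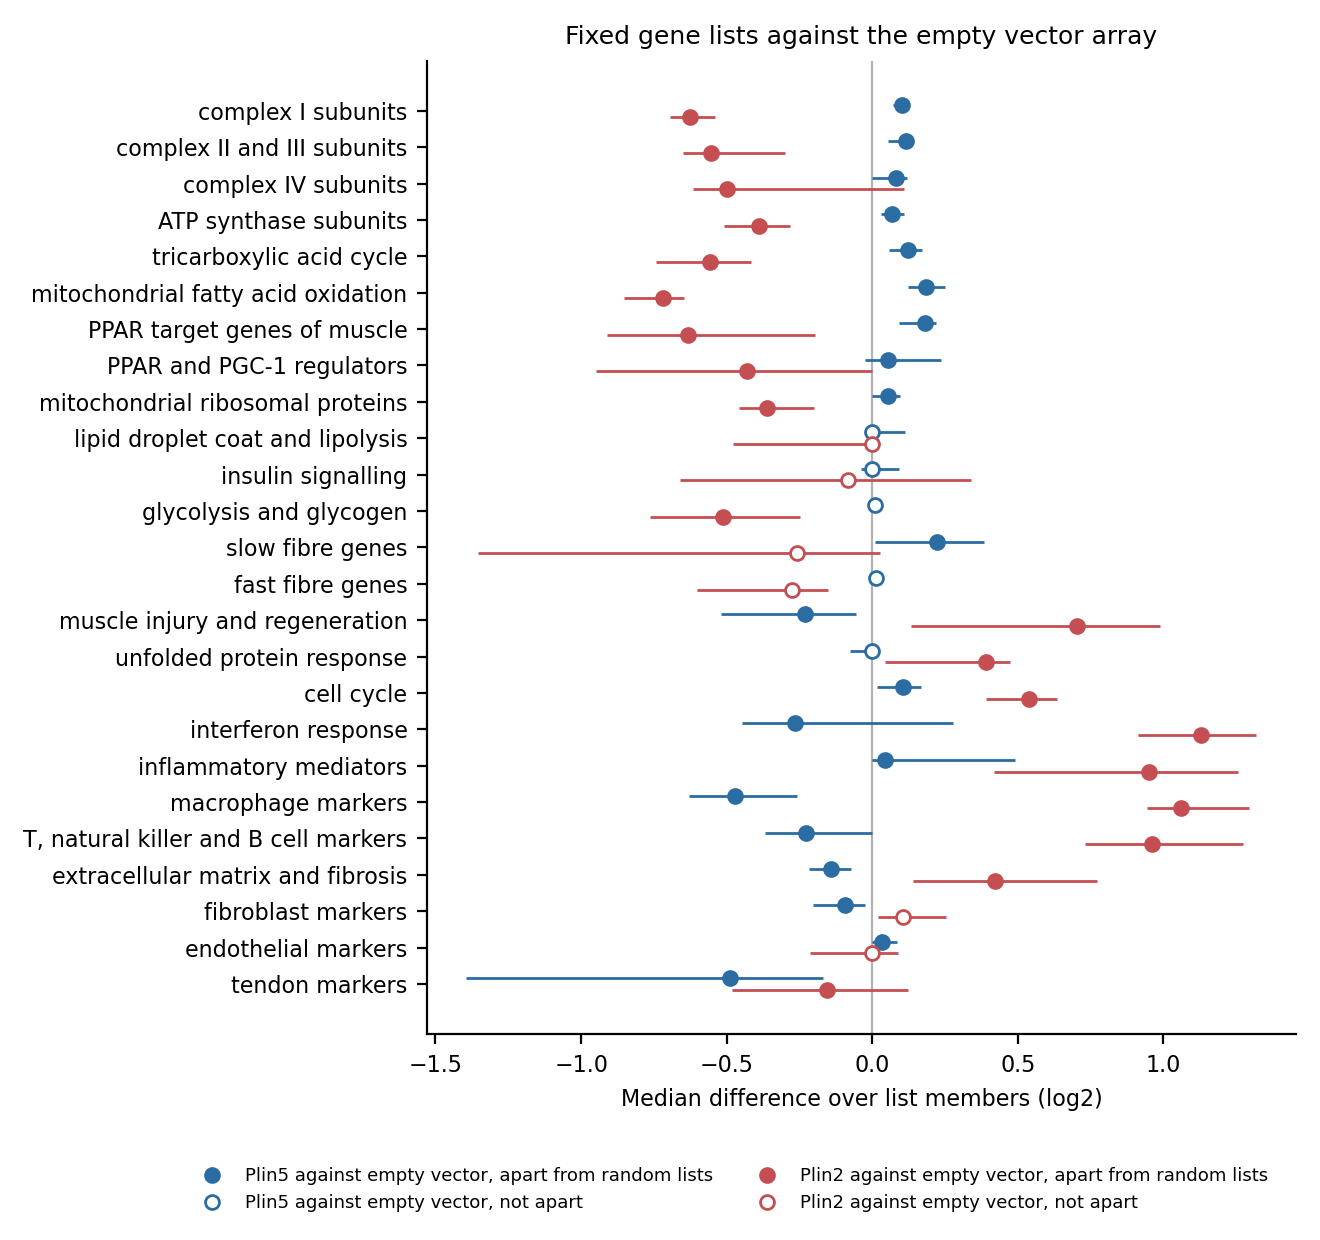
Median log2 difference of 25 of the gene lists on the Plin5 array (blue) and the Plin2 array (red) from the empty vector array; lines are 95% intervals of the median over the genes of a list, which show spread among genes and not among animals, and open circles mark lists that did not stand apart from random lists. Fatty acid oxidation stood at 0.18 on the Plin5 array and −0.72 on the Plin2 array, and macrophage markers at −0.47 and 1.06.

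The direct comparison of Plin5 with Plin2 asked how the arrays of both droplet proteins differed. Genes of oxidative metabolism were higher on the Plin5 array, and immune and regeneration genes were lower. Fatty acid oxidation had a median of 0.85 (1.80-fold), with all 21 genes higher by at least 1.2-fold, and macrophage markers had a median of −1.59. Most of both gaps came from the Plin2 array. Against the empty vector it stood at −0.72 and 1.06 for these lists, and the Plin5 array at 0.18 and −0.47. Backbone and insert differ together in this comparison as well. There were 782 genes higher and 1225 lower by at least 1.5-fold. After median-centring, which shifted the median of all genes by 0.12, the counts were 1109 higher and 979 lower.

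Complex I subunits had a median of 0.72, complex II and III 0.67, complex IV 0.59, ATP synthase 0.46 and the tricarboxylic acid cycle 0.68. Examples were Uqcrq (1.12), Ndufb4 (1.08), Pdhb (1.01), Cox7b (0.93) and Atp5mc1 (0.90). Acadm (1.29), Slc25a20 (1.18), Fabp3 (1.40), Ppara (1.74), Perm1 (2.38) and Ppargc1a (1.03) were higher, and Pparg (−1.04) was lower. Slow fibre genes stood apart (0.56), with Myh7 at 2.19, Myl2 at 2.12 and Myl3 at 1.60. Most of the Myh7 difference was a low value on the Plin2 array (9.42), against 11.17 on the empty vector and 11.60 on the Plin5 array. Glycolysis and glycogen genes had a median of 0.58, with Pfkfb1 at 2.23. The lipid droplet list stood at 0.15, with Fitm2 at 1.39 and G0s2 at 0.72, and no longer stood apart when dim genes were kept (0.00, percentile 52.5); with the dim filter at the median it stood at 0.40. Insulin signalling did not stand apart (0.10, percentile 84.4), with Grb14 at 1.29, Slc2a4 at 1.04 and Pik3cb at −1.08. The largest differences upward were Ostn (2.86), Lgi3 (2.64), Perm1, Pfkfb1 and Aqp4 (2.20).

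Macrophage markers were lower by at least 1.2-fold for 22 of 23 genes, with Trem2 at −3.29 and Mpeg1 at −2.07. Interferon response genes had a median of −1.05 (Mx2 −2.98, Oasl −2.83), lymphocyte markers −1.16 (Gzmk −2.00, Cd8b −1.87) and inflammatory mediators −0.80 (Spp1 −3.21, Il18 −1.83). Regeneration genes had a median of −0.89, including Mymk (−2.64), Chrna1 (−1.64) and Myog (−1.46). The unfolded protein response stood at −0.39, with Asns at −2.20. Tendon markers were lower too (Chad −1.71, Tnmd −0.98). The largest differences downward were Defb52 (−4.37), Hbe1 (−3.95), Cd5l (−3.44), Trem2 and Spp1. Hbe1 (4.68) and Cd5l (4.48) lay under the dim level of 5.34 on the Plin5 array, so the size and rank of their differences are uncertain. In this comparison 17 lists stood apart upward and 14 downward.

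Both perilipin arrays were set against the same empty vector array. Most of the 154 genes lower on the Plin5 array by at least 1.5-fold were higher on the Plin2 array. Most of the 24 genes higher on the Plin5 array were higher on the Plin2 array too. Of 10879 genes, 127 were lower on the Plin5 array and higher on the Plin2 array by at least 1.5-fold. Only Plin5, Ostn and Lgi1 were higher on the Plin5 array and lower on the Plin2 array. Lgi1 was singled out after its values were seen, and it stood at 4.39 on the Plin2 array, under the dim level of 5.34. Independent lists would share 13.6 and 1.39 genes. There were 18 genes higher on both arrays, where independent lists would share 2.12, including Gzma, Ccl12, Spp1, Cxcl11 and Acod1. The only gene lower on both was Kera (−1.03 on the Plin5 and −0.75 on the Plin2 array), where independent lists would share 8.93. Across genes, which are not independent replicates, the correlation of the differences was −0.46 (Spearman −0.50). A shared control alone pushes this value upward: in 100 simulations of unchanged arrays against a shared control the correlation averaged 0.50 (range 0.46 to 0.54). The same simulations gave 29.9 genes higher and 28.9 lower on both arrays, 0.15 higher on Plin5 and lower on Plin2, and 0.20 the other way. All simulated arrays were given equal noise, which sets a correlation near 0.50 by construction. The real differences had unequal spread across genes, with a standard deviation of 0.41 for Plin2 and 0.17 for Plin5. The simulated counts are therefore not a like baseline for the observed counts. The covariance was −0.0320, against a simulated 0.0146. That simulated value was also set by construction, because every Plin5 minus empty vector difference was taken as noise. With 1 control array the control could not be split, so part of any agreement in direction may come from it.

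**Figure D3:**
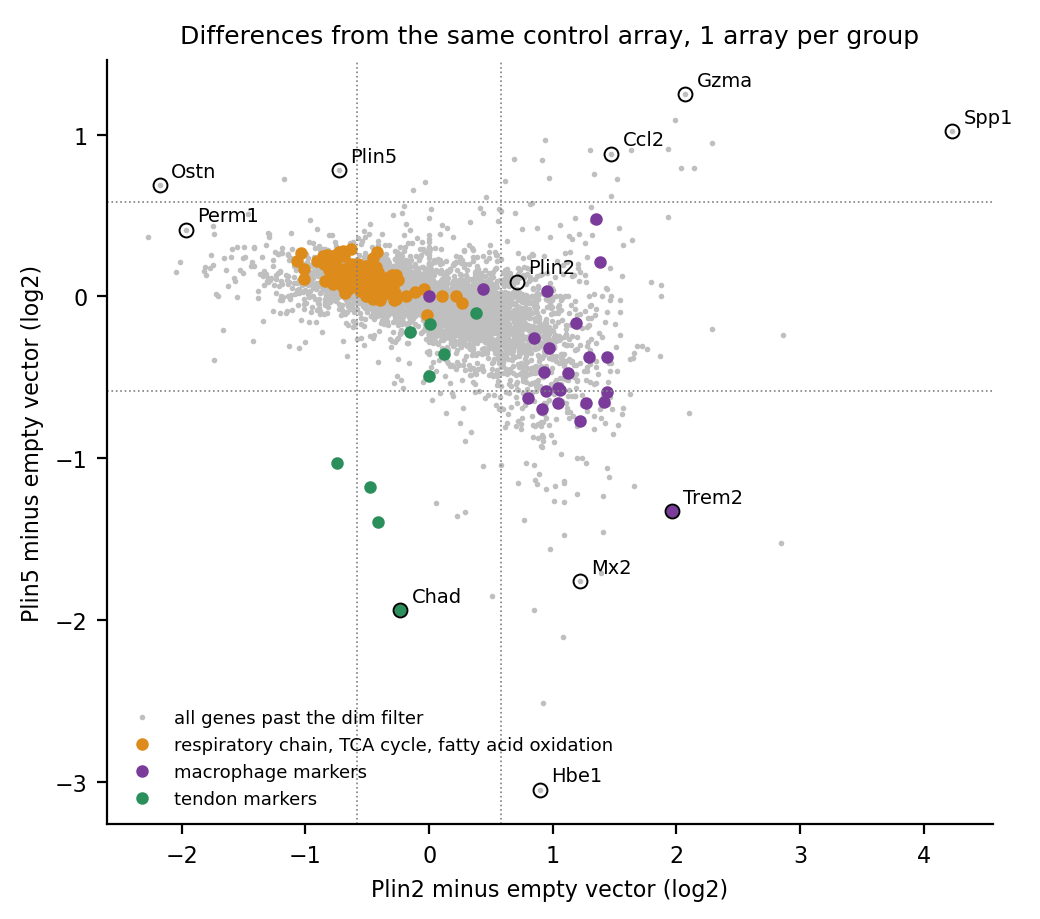
Difference of each of 10879 genes from the empty vector array (log2), on the Plin2 array (x axis) and the Plin5 array (y axis); each point is a gene, coloured points are genes of the fixed lists, circled genes are named, and dotted lines mark 1.5-fold. Most oxidative genes lie to the upper left and macrophage markers to the lower right, with 127 genes past both lines at the lower right and 18 at the upper right.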

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

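The alternatives that left out genes of equal value, took the dim filter from the compared arrays, or left out Plin2 and Plin5 from their lists were chosen after the data were seen. No paired analysis was possible because each group had 1 array. With no replicates, the bounds for calling a value kept were choices made here: 1.5 times for counts, the interval of the median for lists, 0.1 for the correlation and 1.2-fold for single genes. Of 54 gene counts, 42 stayed within bounds. The 12 others came from the fold thresholds, by construction. At 1.3-fold, 69 genes were higher and 372 lower for Plin5 against empty vector, 1582 and 1196 for Plin2 against empty vector, and 1358 and 1869 for Plin5 against Plin2. At 2-fold these were 3 and 40, 272 and 142, and 215 and 562. The correlation ranged from −0.52 to −0.44. All 1848 values of named genes stayed within 1.2-fold of the reported ones. The settings shifted the median of all genes by no more than 0.12 log2 units, under that bound of 0.26. This outcome was therefore nearly given in advance and does not show how reliable a difference between single arrays is. Of 1238 list medians, 1204 stayed within bounds, 34 moved, and none of those that stood apart changed sign.

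Median-centring, which shifted the median of all genes by 0.04, −0.08 and 0.12 in the 3 comparisons, moved these medians by its construction. For Plin5 against empty vector, complex I stood at 0.14, complex II and III at 0.15, complex IV at 0.12, PPAR targets at 0.22 and cytosolic ribosomal proteins at −0.038. For Plin2 against empty vector, complex I stood at −0.71 and cytosolic ribosomal proteins at 0.073. For Plin5 against Plin2, complex I stood at 0.84, complex II and III at 0.80, complex IV at 0.71, cytosolic ribosomal proteins at −0.11 and the circadian clock at 0.42. It also moved the share of higher genes from 60.4% to 48.6% for Plin2 against empty vector and from 39.0% to 53.1% for Plin5 against Plin2. In 19 cases a list stopped standing apart: 8 for Plin5 against empty vector (6 of 27 lists), 9 for Plin2 against empty vector (5 of 29) and 2 for Plin5 against Plin2 (2 of 31); the cause was not tested. Dim genes and small differences carry the least information, since signal over background could not be measured from these values.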

Other observations

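Of the tests here, only the test of interferon genes was written before its result was seen; the others were chosen after the pattern was known. Further gene groups differed between arrays. On the Plin5 array, cell cycle genes were higher than on the empty vector array (median 0.11, 19 of 23 above 0), with Ccna2 at 0.34 and Bub1 at 0.27, although they were also higher on the Plin2 array. Endothelial markers had a median of 0.04, with Flt1 at 0.25, and smooth muscle markers 0.03, a list that did not stand apart with the dim filter at the median (0.02, percentile 95.7). Antigen presentation genes had a median of −0.16, with the class II gene RT1-Da at −0.59. Fibroblast markers had a median of −0.09 and lysosome genes −0.04, but by their means neither stood apart (percentiles 3.34 and 5.85). Erythroid genes (−0.10) did not stand apart by their mean (percentile 13.4). After median-centring, endothelial and smooth muscle markers stood at 0.07, fibroblast markers at −0.05, erythroid genes at −0.06 and lysosome genes at −0.00058 (−0.13 with tied genes left out). Lists for cholesterol, fatty acid, sphingolipid and triacylglycerol synthesis, proteasome, adipocyte, Schwann cell, satellite cell and mast cell genes, atrophy, oxidative stress and immediate early genes had medians of 0.00. Heat shock (0.02), clock (0.01) and unfolded protein response genes did not stand apart.

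On the Plin2 array, several regulatory and structural groups differed from the empty vector. Clock genes were lower (median −0.25, 15 of 16 below 0), with Nr1d1 at −1.23 and Nr1d2 at −0.53, against 0.63 for Per1. Erythroid genes had a median of −0.74 (−0.41 when dim genes were kept), with Hbb-b1 at −1.26 and the heme enzyme Alas2 at −1.04. Peroxisomal fatty acid oxidation stood at −0.40 (−0.60 with tied genes left out), with Abcd2 at −0.92. Satellite cell markers stood at 0.30, with Cdh15 at 0.88, lysosome genes at 0.24 (0.15 after median-centring), with Ctsz at 1.18, and cytosolic ribosomal proteins at 0.16 (0.073 after median-centring), with Rpl3 at 0.70. Triacylglycerol and phospholipid synthesis stood at −0.18 (−0.11 when dim genes were kept), with Lpin1 at −1.22 and Gpam at −0.75, and did not stand apart with tied genes left out (percentile 2.60). Tendon markers (−0.15) and immediate early genes (0.14) did not stand apart by their means (percentiles 4.72 and 94.0), and stood at −0.24 and 0.06 after median-centring; with tied genes left out immediate early genes stood at 0.30. A set of 9 genes was at least 1.5-fold lower on the Plin5 array while they differed by less than 1.2-fold on the Plin2 array, among them Chad and, chosen after their values were seen, Cd72 (−1.35) and Ppef1 (−1.28).

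Interferon genes parted on the Plin5 array. In the fixed list, Mx and Oas genes were lower and Cxcl9 was higher, which may reflect targets of type I interferon and of interferon gamma. The hypothesis was tested on genes outside the fixed lists. These were read on the same array and include further Oas genes, so they are not independent of the pattern that prompted the test. The median of 26 type I targets was −0.20 (interval −0.36 to −0.11), with 25 below 0 and 0 above 0, including Oas2 (−1.15) and Zbp1 (−0.69). The median of 14 interferon gamma targets was 0.01 (interval −0.10 to 0.42), with Irgm at 0.57 and Irf8 at −0.51. The difference of 0.20 went the way of the hypothesis, but the intervals were barely apart and the gamma targets did not themselves stand apart from random lists (percentile 95.3). On the Plin2 array both sets were higher, by 0.92 and 0.60. With 1 pool of rats per group, differences between the animals pooled remain open beside an effect of Plin5.

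On the Plin2 array immune genes were higher and oxidative genes lower; a lower share of muscle fibre RNA alone would raise markers of all other cells alike, but macrophage markers exceeded endothelial markers by 1.06, with intervals of 0.94 to 1.29 and −0.21 to 0.09. RNA from more macrophages remains a candidate explanation of the immune part. Of measured markers, 95.7% were higher by at least 1.2-fold, including the abundant Lyz2 (11.96 to 12.91) and Fcer1g (11.65 to 12.46). These are the markers that showed the pattern, so that share adds no separate support. All 23 markers already lay above the dim level on the empty vector array and 0 are in another list. Added macrophage RNA as the only change would have lowered endothelial markers as far as fatty acid oxidation. Fatty acid oxidation lay below them by a difference of −0.72 with intervals apart, though these lists were not matched on level. Dilution of fibre RNA by a wider mix of cells cannot be told apart from a change within fibres: fatty acid oxidation differed by −0.21 from all glycolysis genes and by 0.046 from the 13 of similar or lower level, with overlapping intervals, and the smaller fast fibre difference (−0.27) rests on genes of which 13 of 15 were brighter than any of fatty acid oxidation and may be compressed. Nor can the Plin2 insert be told apart from its plasmid backbone or its pool of rats, because 1 array carried that plasmid.

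On the Plin5 array oxidative and slow fibre genes were slightly higher and macrophage and tendon markers lower; a larger share of muscle fibre RNA alone would lower markers of all other cells alike, but macrophage markers differed from endothelial markers by −0.51, with intervals of −0.63 to −0.26 and 0.00 to 0.09. Less macrophage RNA as the only change would have raised endothelial markers as far as fatty acid oxidation. The latter exceeded them by 0.15, with intervals apart. That gap does not settle the question, as the lists were not matched on level and 3 of 17 endothelial genes had equal values. With tied genes left out the endothelial median was 0.07. A larger fibre share beside other changes in the cell mix cannot be told apart from a change within fibres as the source of the oxidative difference: fatty acid oxidation exceeded all glycolysis genes by 0.17 with intervals apart, but bright genes may be compressed, and it exceeded the 13 glycolysis genes of similar or lower level by 0.15 with overlapping intervals (0.12 to 0.25 and 0.00 to 0.19). More slow fibre in the sampled tissue also remains open, since slow fibre genes exceeded fast fibre genes by 0.21 with overlapping intervals (0.01 to 0.38 and −0.00425 to 0.03). Whether the muscle pieces differed in tendon content, with Chad at −1.94, was not tested, nor was an effect of Plin5 itself, as each group was a single pool.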
